A study of Mus musculus with 7 samples.

How the data were processed

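RNA from 7 samples of allografted mouse prostate tumours was amplified, labelled with biotin and hybridised to Illumina mouse bead arrays, with 1 array per sample. Each sample is taken here as a separate tumour. Per the labels, 3 tumours came from mice given vehicle and 4 from mice given RAPPD, daily for 5 days, with harvest on the fifth day. The deposited table of the whole series gave 1 background-subtracted intensity on a linear scale for each of 45128 probes on each array, without detection p-values, bead counts or control probes. BeadStudio and lumi are named, without versions, in the submitters' processing notes, and the role of each is not given in the sources used here. Between 28.8% and 30.3% of the intensities on an array were below 0. The mean intensity per array lay between 498.1 and 501.9, so a scaling between arrays before export cannot be excluded.

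A further deposited table held the submitters' processed values, read here as log2-like values. Within each array they followed the order of that array's intensities (rank correlation at least 0.99999 across probes). Their slope on log2 intensity was 1.02 above an intensity of 2000, and they flattened towards the low end. Their medians were 8.023, 8.025 and 8.023 for vehicle 1 to 3 and 8.021, 8.022, 8.022 and 8.022 for RAPPD 1 to 4. The exact transform and any centring of these values stay unknown, and they served only as an alternative.

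The plan made before the data were examined called for limma's neqc, which needs detection p-values or control probes. Since neither was in the table, the same kind of correction was made from the intensities: normexp with the background mean set at 0 and its SD estimated per array from the negative intensities, which gave SDs of 8.41 to 9.35. An offset of 16 was added, arrays were quantile normalised together and values were taken to log2. A probe was called detected on an array when its intensity exceeded the upper 0.05 tail of that background. By this measure 20323 to 21330 probes were detected per array (45.0% to 47.3%), and for arrays the number of tumours limits the precision. Probes detected on at least 3 arrays were kept (21249 probes).

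Probes were named through the platform annotation supplied for the value table. Of the 45128 probes, 34776 had 1 gene symbol, 18 had several and 10334 were unnamed here. Symbols were looked up through Entrez identifiers in a RefSeq gene table of assembly GRCm38.p6, where 99.72% of them matched and 0 changed. No genome build is named in the sources used here, so no coordinates are printed. A gene was represented by its probe with the highest mean, which left 11085 genes, of which 4469 had several probes past the filter. Other probes of a named gene are given where 1 of them lay over 1 log2 unit from the probe used, or inside a bound, a rule set after the values were seen.

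RAPPD tumours were compared with vehicle tumours by limma 3.58.1 (lmFit and eBayes, R 4.3.3) on all 7 arrays, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. All adjusted p-values below are from limma. A gene that was not detected on any array of its lower group has a bound in place of a fold change, taken from the mean of the higher group and the mean detection limit of the arrays of the lower group, and is written as at least N-fold. Fixed gene lists (34, of which 13 were cell type markers) were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the 34 lists. Camera with an estimated correlation and fry were alternatives. Counts adjusted over the list alone use the members of the list as the family of tests. Some genes belong to several lists, so the lists are not independent of each other.

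The named genes were fixed by a rule before the data were examined. They are the 8 largest rises and 8 largest falls among genes past the threshold whose groups do not overlap and which were detected on every array of the higher group. Unnamed gene models were passed over. Added to these are 10 readouts chosen in advance, and the members with the smallest p in each list, up to 3 in the direction of a called list and up to 2 in a list that was not called. Exceptions within a list were named after their values were seen.

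The array positions in the labels place the samples on 3 chips. Vehicle 1 and vehicle 2 were each alone on a chip, and vehicle 3 shared a chip with the 4 RAPPD arrays. Chip was therefore fitted as a fixed block, which leaves 1 vehicle and 4 RAPPD arrays of the shared chip, and as a random block with duplicateCorrelation (statmod 1.5.0, correlation 0.332). Replicate numbers within a group follow the order of the series and pair nothing. The labels do not say whether the tumours of a group came from separate donor tumours or mice, so p-values measure the spread between these 7 samples.

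Alternatives were another background offset (50), no background correction, median scaling, cyclic loess, the submitters' processed values, no filter, a stricter filter, the mean of a gene's probes, a variance trend, array weights, both chip fits, other thresholds, all probes, other list tests and leaving out each array. A normexp fit to the intensities, scaling to the 75th percentile and a fit without vehicle 2 and 3 were added after seeing the data. The fit without vehicle 2, planned among those leaving out each array, was entered again then. The fit was tested on simulated data for RAPPD minus vehicle, with 4 against 3 arrays and 11085 genes. It called 58% of simulated 2-fold changes and 89% of simulated 4-fold changes, and 6.83% of the calls fell on unchanged genes. These simulated changes covered a small share of the genes, left out the dimmest genes and held no chip effect. The percentages therefore need not hold for dim genes or for the larger share of genes called here. The list test called a list raised by a known shift and 0 other lists. The simulated genes were independent of each other, so this does not test false list calls among correlated genes.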

Results

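Gene expression was measured in prostate tumours of the NPK mouse model grown as allografts in athymic nude mice of the NU/J strain, which lack a functional thymus. Mice received vehicle (3 tumours) or RAPPD (4 tumours) daily for 5 days. The labels do not spell out RAPPD. In the published work on this model the name stands for rapamycin, an inhibitor of mTOR, given with an inhibitor of the kinase MEK. Between 20323 and 21330 of 45128 probes were detected per array. Across the genes tested, Pearson's r between arrays was 0.955 to 0.974 within the vehicle group, 0.970 to 0.986 within the RAPPD group and 0.904 to 0.950 between groups. Genes are not independent replicates. The first principal component held 62.4% of the variance and placed the vehicle arrays at -56.9 to -35.8 and the RAPPD arrays at 19.7 to 47.9.

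The comparison asked which transcripts differed after the short treatment. RAPPD tumours had lower levels of genes of mitosis and DNA replication (adjusted p = 0.044 and 0.0301 with an estimated correlation). Lists of ERK pathway readouts, of ATF4 and amino acid supply and of ribosome biogenesis were also called lower, but these calls were lost with an estimated correlation (adjusted p = 0.391, 0.275 and 0.0527). Neutrophil, inflammatory and red blood cell lists were called higher, and these calls were lost in the same way (adjusted p = 0.409, 0.275 and 0.615 with an estimated correlation). The mitotic kinase Plk1 fell by 5.00 ± 0.25 on the log2 scale (SE, n = 4 and 3), which is 31.9-fold. Its difference ranged from -5.53 to -2.44 over the alternatives. The neutrophil-attracting chemokine Cxcl2 rose by 5.89 ± 0.72, which is 59.1-fold, with another probe of the gene at 1.90. Its rise was 4.25 with chip as a fixed block, since vehicle 3 (7.68) stood above vehicle 1 and 2 (5.30 and 5.16).

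Of 11085 genes tested, 1214 were higher and 1457 lower in RAPPD tumours at an adjusted p under 0.05 (limma), and 174 and 186 of the genes called in each direction differed at least 4-fold. The groups did not overlap for 2600 of the 2671 called genes. Over all tested genes this share was 34.7%, where chance gives 5.71%. The median difference of all genes was -0.014. With chip as a fixed block, which sets vehicle 3 against the 4 RAPPD arrays of its chip, 379 genes were higher and 659 lower. Of the 2671 called genes, 855 were called there. Of the 91 named genes called on all arrays, 30 were not called in that fit, and they are given with their lists and their differences in that fit. It leaves 1 vehicle array and mostly has larger standard errors, so a lost call alone does not speak for an effect of chip. Chip as a random block gave 948 higher and 1260 lower genes. Leaving out vehicle 1 gave 752 and 896.

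**Figure D1:**
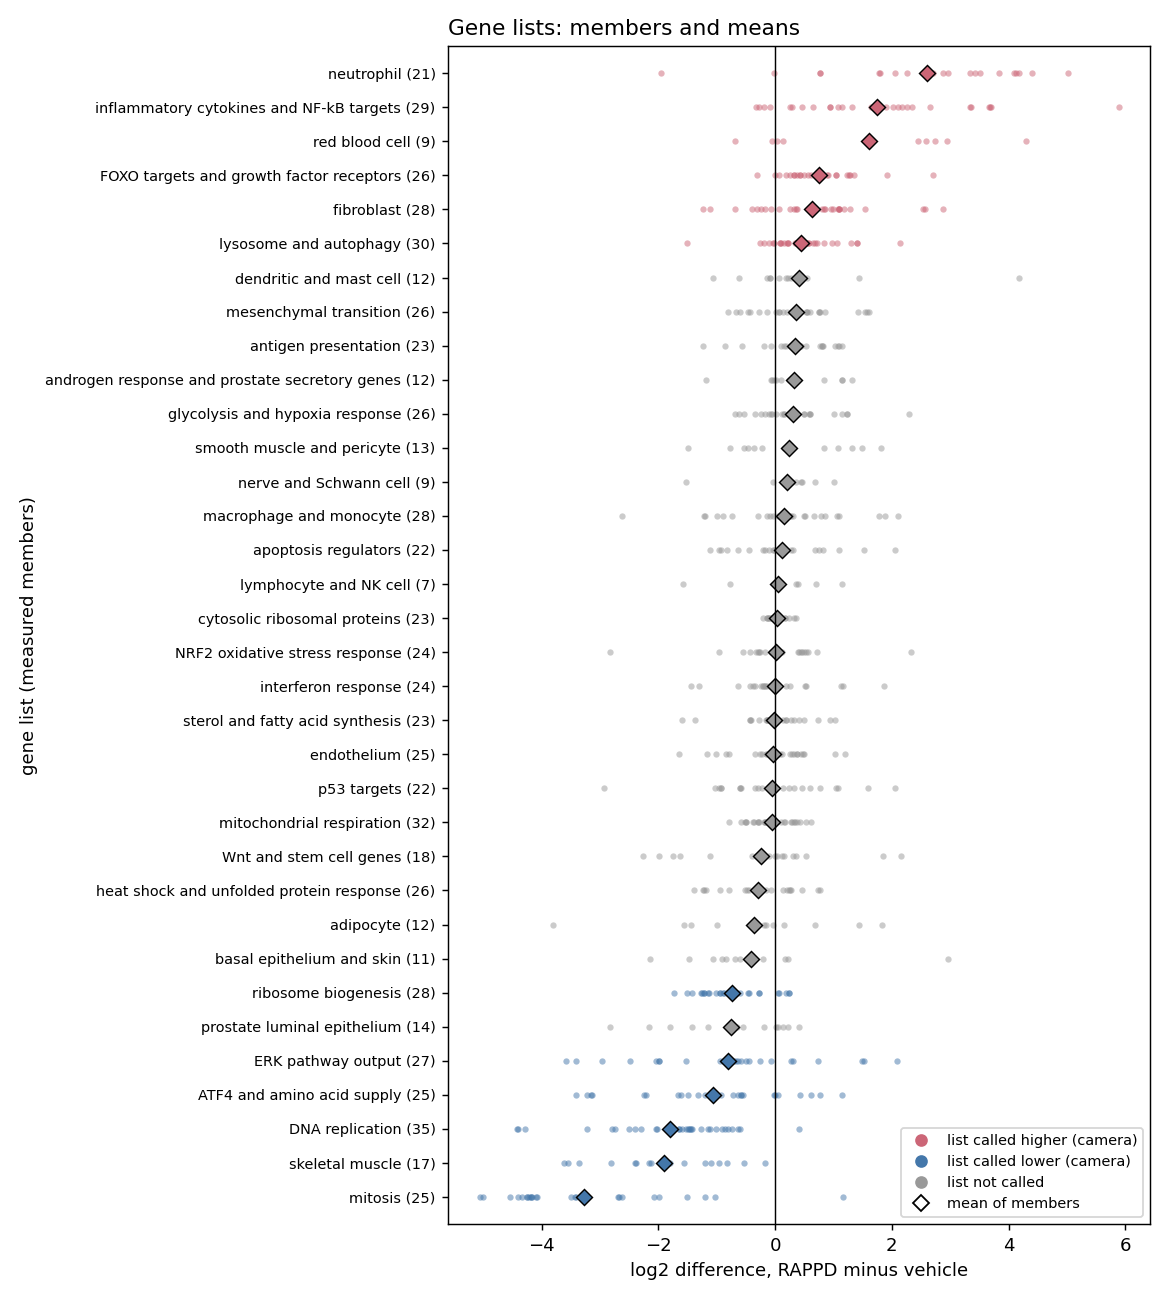
Log2 difference between RAPPD and vehicle tumours (x axis) for each measured member of the 34 gene lists (small points, rows, number of measured members in brackets) and their mean (diamonds), with called lists in red (higher) or blue (lower) and others in grey. Mitosis lies lowest with a mean of -3.27 and neutrophil highest with a mean of 2.60.

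Of the 34 lists, mitosis had the lowest mean and DNA replication was also called lower. Of 25 measured mitosis genes, 24 fell and 1 rose, with the same counts adjusted over the list alone. Their mean was -3.27 and their median -4.07 (camera adjusted p = 7.41e-25, and adjusted p = 0.044 with an estimated correlation). The mean was -3.07 with chip as a fixed block (adjusted p = 2.41e-22), where all 24 that fell were called. The kinases Aurka fell by 4.33 ± 0.17, Aurkb fell by 4.18 ± 0.16, and Birc5 (survivin) fell by 4.41 ± 0.19. Aurkb was above background on 1 of the 4 RAPPD arrays, so the floor limits the size of its fall. The transcription factor Foxm1, which drives many mitotic genes, fell by 2.67 ± 0.18 (6.35-fold). The centromere protein gene Cenpf was not above background on any RAPPD array and was at least 1.73-fold lower by the probe used (adjusted p = 8.83e-04), with its other probe at -0.63. The single member that rose, Kif23, named after its values were seen, is not settled by its probes: the brightest rose by 1.16 ± 0.31, while the others lay at -4.72 and -4.32. Its call was lost with chip as a fixed block (0.96 ± 0.44, adjusted p = 0.211).

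Of 35 measured DNA replication genes, 32 fell and 0 rose (34 fell adjusted over the list alone), with a mean of -1.79 (camera adjusted p = 2.64e-22, and adjusted p = 0.0301 with an estimated correlation). The mean was -1.72 with chip as a fixed block (adjusted p = 1.91e-18), where 27 of the 32 that fell were called. Uhrf1, which couples replication to DNA methylation, fell by 4.40 ± 0.18, and the replicative helicase subunit gene Mcm5 fell by 4.29 ± 0.17. Thymidine kinase Tk1 fell by 4.42 ± 0.20, although its other probes ranged from -2.09 to 0.11.

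The 8 largest falls were Pbk (fell by 5.16 ± 0.20, 35.8-fold), the kinesin Kif2c (fell by 5.05 ± 0.28), Plk1, Troap, Kif18b (fell by 4.62 ± 0.23, other probes -3.81 to -1.25), the chromosomal passenger gene Cdca8 (fell by 4.54 ± 0.22), the checkpoint adaptor Clspn (fell by 4.51 ± 0.28) and the recombination gene Rad54b. Troap and Rad54b were not above background on any RAPPD array and were at least 22.8-fold and 19.6-fold lower by the probes used, with another probe of Troap at -3.41. Kif18b and Clspn were above background on 2 and 1 of the 4 RAPPD arrays, so the floor limits the size of their falls. The adjusted p of these 8 genes was at most 2.08e-05. In the same tumours the luminal keratin Krt8 fell by 2.16 ± 0.29 and its partner Krt18 fell by 2.83 ± 0.48, while the luminal list as a whole was not called (mean -0.76, adjusted p = 0.168). The calls of Krt8 and Krt18 were lost with chip as a fixed block (-2.03 ± 0.47 and -1.89 ± 0.64, adjusted p = 0.0512 and 0.12).

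**Figure D2:**
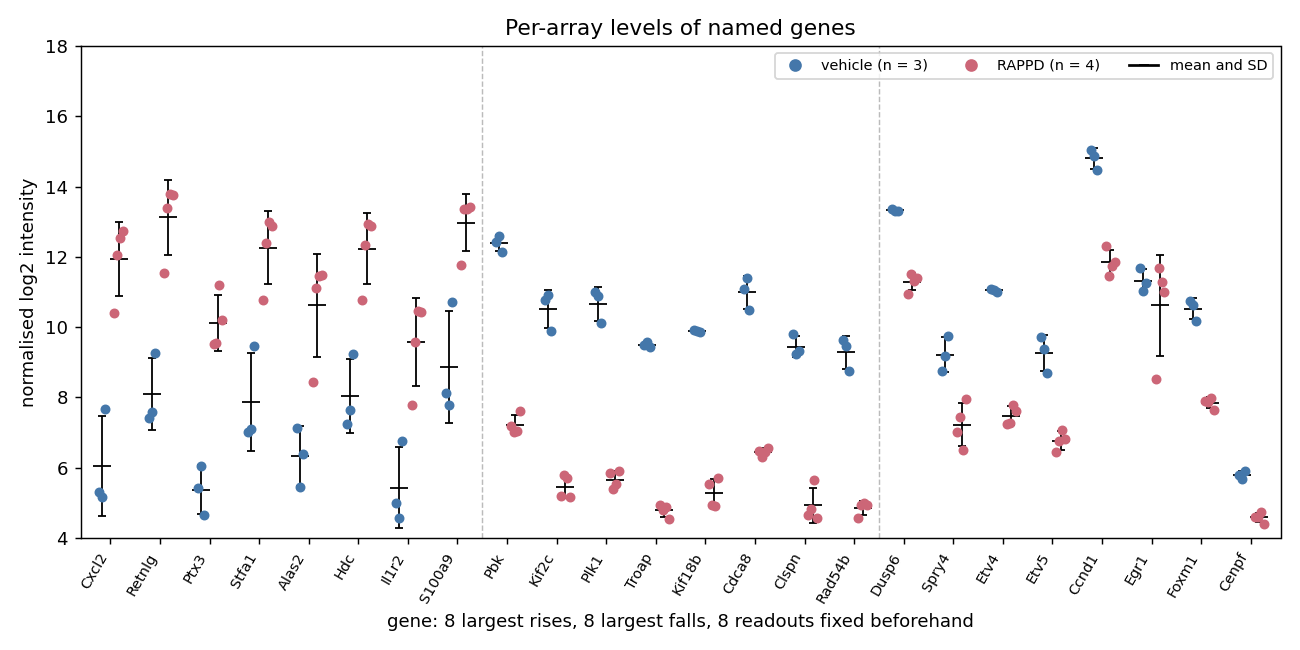
Normalised log2 intensity (y axis) of the 8 largest rises, the 8 largest falls and the 8 tested readouts fixed beforehand (x axis), with 1 point per array in blue for vehicle (n = 3) and red for RAPPD (n = 4), and bars for mean and SD. Plk1 averages 10.66 in vehicle and 5.67 in RAPPD tumours, while Egr1 overlaps between groups.

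Readouts of the ERK pathway, fixed beforehand, were lower with exceptions. Of 27 measured members of the list, 15 fell and 3 rose (17 and 4 adjusted over the list alone), with a mean of -0.80. The camera adjusted p was 6.19e-04, and the call was lost with an estimated correlation (adjusted p = 0.391 with an estimated correlation). The mean was -0.66 with chip as a fixed block (adjusted p = 0.00955), where 8 of the 15 that fell and 0 of the 3 that rose were called. The ERK phosphatase Dusp6 fell by 2.03 ± 0.17 (4.09-fold), and the feedback inhibitor Spry4 fell by 1.99 ± 0.36. The ETS factor Etv4 fell by 3.58 ± 0.18 and Etv5 fell by 2.49 ± 0.26. Cyclin D1 (Ccnd1) fell by 2.96 ± 0.23, from a mean of 14.80 to 11.84. The immediate-early gene Egr1 was not called (-0.71 ± 0.67, adjusted p = 0.474), and its difference rested on RAPPD 1 (8.51, against 11 to 11.67 on the other RAPPD arrays, and -0.0098 without it). The members that rose, named after their values were seen, were the immediate-early genes Ier3 (2.09 ± 0.31) and Fos (1.53 ± 0.33) and the cytokine Lif (2.82-fold). The readout Spry2 did not pass the filter, and Mki67 was not analysed here.

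Genes of the ATF4 response and amino acid supply were lower. Of 25 measured, 15 fell and 2 rose (16 and 2 adjusted over the list alone), with a mean of -1.07 (camera adjusted p = 3.93e-05, and adjusted p = 0.275 with an estimated correlation). The mean was -0.66 with chip as a fixed block (adjusted p = 0.00165), where 7 of the 15 that fell and 0 of the 2 that rose were called. Psat1 of serine synthesis fell by 3.23 ± 0.21, mitochondrial one-carbon enzyme Mthfd2 fell by 3.40 ± 0.30 and proline synthesis enzyme Aldh18a1 fell by 1.61 ± 0.17. The members that rose, named after their values were seen, were Cebpb (1.15 ± 0.21) and the mTOR inhibitor gene Ddit4 (0.77 ± 0.24).

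Ribosome biogenesis genes fell in 19 of 28 cases and rose in 0 (20 fell adjusted over the list alone), with a mean of -0.75 (camera adjusted p = 2.48e-07, and adjusted p = 0.0527 with an estimated correlation). The mean was -0.82 with chip as a fixed block (adjusted p = 3.04e-07), where 9 of the 19 that fell were called. Nucleolin (Ncl) fell by 1.73 ± 0.18, and the nucleolar protein gene Nop2 fell by 1.43 ± 0.14 and Nop56 fell by 1.52 ± 0.18. Of 23 cytosolic ribosomal protein genes, 0 passed the test (0 adjusted over the list alone). Their mean was 0.030, their median -0.0022 and the test pointed up (adjusted p = 0.770).

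Neutrophil transcripts were higher in RAPPD tumours. Of 21 measured markers, 16 rose and 1 fell (17 and 1 adjusted over the list alone), with a mean of 2.60 (camera adjusted p = 1.52e-08, and adjusted p = 0.409 with an estimated correlation). The mean was 1.71 with chip as a fixed block (adjusted p = 5.56e-05), where 2 of the 16 that rose were called and vehicle 3 had a list mean of 8.41 against 7.16 and 6.99 in the other vehicle arrays. Retnlg rose by 5.03 ± 0.62 (32.6-fold) and the lectin Clec4e by 3.52 ± 0.36. With chip as a fixed block they rose by 3.85 and 2.74. The histamine-forming enzyme Hdc rose by 4.18 ± 0.61, the decoy receptor Il1r2 by 4.13 ± 0.72 and the calprotectin subunits S100a8 and S100a9 by 2.96 ± 0.50 and 4.10 ± 0.70. Il1r2 was above background on 1 of the 3 vehicle arrays, so the floor limits the size of its rise. The protease inhibitor Stfa1 rose by 4.40 ± 0.70 and belongs to a family of near-identical genes, so its identity is uncertain. The exception, named after its value was seen, was Padi4, which fell by 1.95 ± 0.37. The calls of Stfa1, Hdc, Il1r2, S100a8, S100a9 and Padi4 were lost with chip as a fixed block (2.79 ± 0.84, 2.98 ± 0.81, 2.82 ± 1.0, 1.77 ± 0.54, 2.27 ± 0.66 and -1.12 ± 0.42, adjusted p 0.0734 to 0.146).

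Inflammatory cytokines and NF-kB targets rose in 19 of 29 cases and fell in 0 (22 rose adjusted over the list alone), with a mean of 1.74 (camera adjusted p = 6.32e-10, and adjusted p = 0.275 with an estimated correlation). The mean was 1.32 with chip as a fixed block (adjusted p = 5.31e-07), where 9 of the 19 that rose were called. The chemokine Cxcl1 rose by 3.66 ± 0.41 and the NF-kB inhibitor Nfkbia by 2.17 ± 0.23. The nitric oxide synthase Nos2 rose by 3.36 ± 0.34, with its other probe at 0.46. The soluble pattern recognition protein Ptx3 rose by 4.75 ± 0.46 (26.9-fold). Nos2 and Ptx3 were above background on 2 of the 3 vehicle arrays, so the floor limits the size of their rises. The inflammatory and neutrophil lists share Il1b, Cxcl3 and Lcn2.

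Red blood cell transcripts were also higher. Of 9 measured, 5 rose and 0 fell (5 adjusted over the list alone), with a mean of 1.61 (camera adjusted p = 0.01, and adjusted p = 0.615 with an estimated correlation). The erythroid haem synthesis enzyme Alas2 rose by 4.29 ± 0.74, and the alpha globin Hba-a1 by 2.74 ± 0.36. The beta globins Hbb-bt and Hbb-bs rose by 2.59 ± 0.32 and 2.46 ± 0.33 and cannot be separated with certainty, being near-identical (other probes of Hbb-bs 2.78 to 4.67). Hbb-bs reached 15.85 on RAPPD 3 and 4, near the top of the scale, where a rise can be compressed. With chip as a fixed block the mean was 1.61 (adjusted p = 0.164), 3 of the 5 that rose were called, and the call of Alas2 was lost at a similar size (4.22 ± 1.17, adjusted p = 0.0762). Without vehicle 2 the mean was 1.46 (adjusted p = 0.0688).

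FOXO targets and growth factor receptor genes rose in 11 of 26 cases and fell in 0 (12 rose adjusted over the list alone), with a mean of 0.76 (camera adjusted p = 4.98e-06, and adjusted p = 0.171 with an estimated correlation). The mean was 0.80 with chip as a fixed block (adjusted p = 6.59e-06), where 5 of the 11 that rose were called. The stress gene Gadd45b rose by 2.70 ± 0.21 (other probe 0.76), the transcription factor Foxo1 by 1.27 ± 0.15 and the atypical cyclin Ccng2 by 1.22 ± 0.15. Lysosome and autophagy genes rose in 9 of 30 cases and fell in 1 (11 and 1 adjusted over the list alone), with a mean of 0.45 (camera adjusted p = 9.28e-04, and adjusted p = 0.275 with an estimated correlation). The mean was 0.40 with chip as a fixed block (adjusted p = 0.00656), where 1 of the 9 that rose and 0 of the 1 that fell were called. The mitophagy receptor Bnip3l rose by 1.06 ± 0.16, Map1lc3a of the autophagosome by 0.84 ± 0.16 and the sialidase Neu1 by 1.31 ± 0.25. The exception, named after its value was seen, was Atg9b, which fell by 1.52 ± 0.24. The calls of Bnip3l, Map1lc3a, Neu1 and Atg9b were lost with chip as a fixed block (0.91 ± 0.22, 0.86 ± 0.23, 0.78 ± 0.29 and -1.25 ± 0.34, adjusted p = 0.0542, 0.0666, 0.147 and 0.0762).

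**Figure D3:**
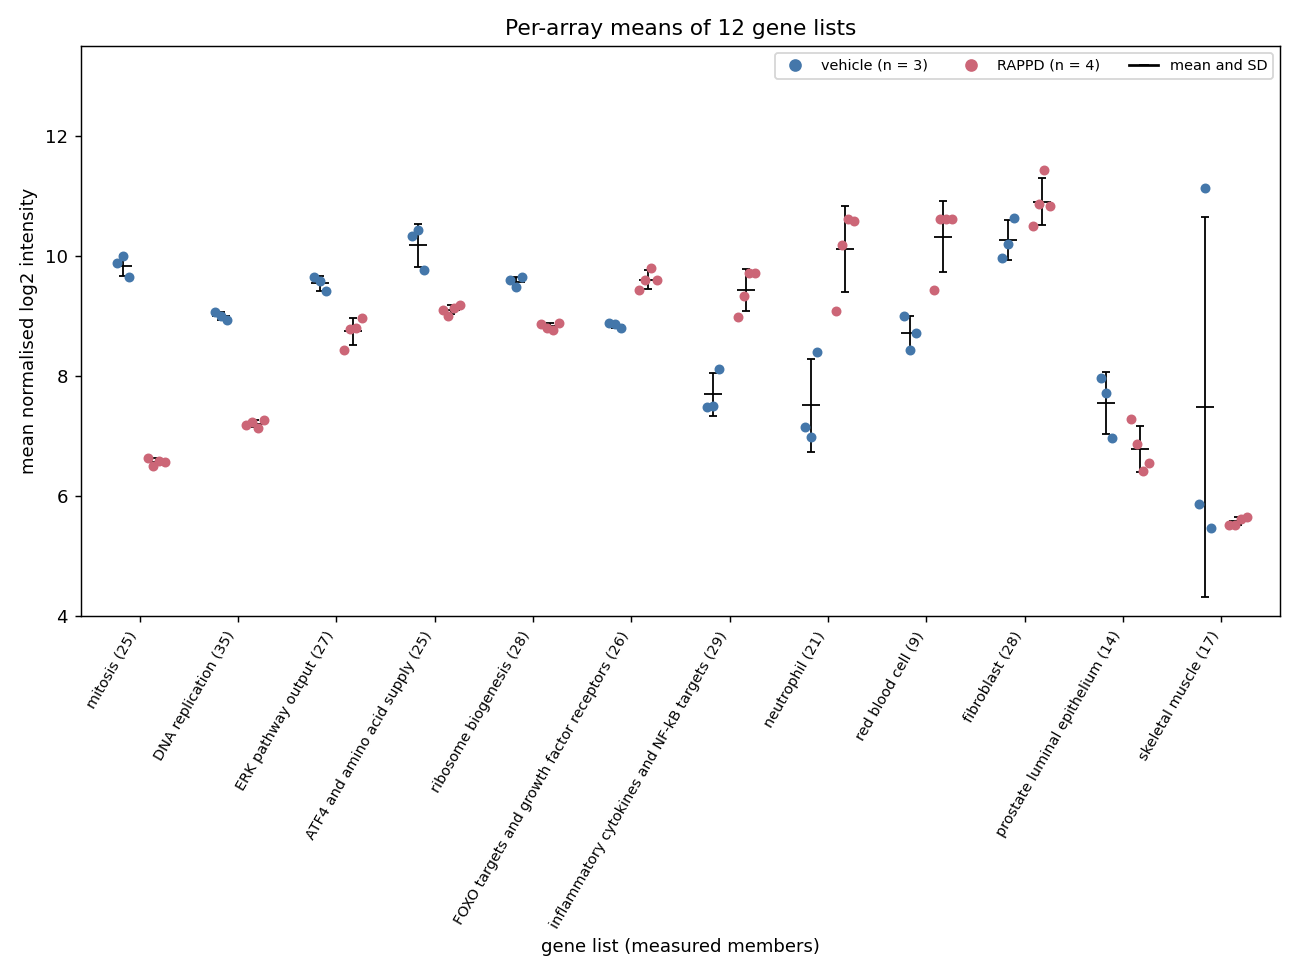
Mean normalised log2 intensity (y axis) of the members of 12 gene lists (x axis, number of measured members in brackets) on each array, in blue for vehicle (n = 3) and red for RAPPD (n = 4), with bars for the group mean and SD. The skeletal muscle mean is 11.13 on vehicle 2 and 5.46 to 5.86 on the other arrays.

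Markers of host tissue differed between arrays as well as groups. The skeletal muscle list was called lower (mean -1.91, camera adjusted p = 0.0317, and adjusted p = 0.831 with an estimated correlation), with 1 of 17 members called (1 adjusted over the list alone). It rested on vehicle 2, whose list mean was 11.13 against 5.46 to 5.86 on the other 6 arrays. Without vehicle 2 the mean was -0.094 (adjusted p = 0.971), and with chip as a fixed block it was 0.12. The call was also lost without RAPPD 1 (-2.18, adjusted p = 0.0819) or RAPPD 4 (-1.81, adjusted p = 0.0764). The called member was the muscle enolase Eno3, which fell by 1.84 ± 0.34. Its fall did not rest on vehicle 2 (12.15) alone. Vehicle 1 and 3 stood at 10.75 and 10.96, against 9.25 to 9.911 on the RAPPD arrays. Without vehicle 2, 837 genes were higher and 1114 lower, and 1784 of the 2671 calls were kept.

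Fibroblast genes rose in 6 of 28 cases and fell in 3 (6 and 3 adjusted over the list alone), with a mean of 0.64 (camera adjusted p = 0.0317, and adjusted p = 0.678 with an estimated correlation). The small proteoglycan Ogn rose by 2.87 ± 0.42, the collagen cross-linking enzyme Lox by 2.53 ± 0.45 and the collagen gene Col1a2 by 2.57 ± 0.56. The list was not called without vehicle 1 (0.53, adjusted p = 0.113), vehicle 2 (0.62, adjusted p = 0.0688) or RAPPD 3 (0.51, adjusted p = 0.0668), nor with chip as a fixed block (0.28, adjusted p = 0.779), where 0 of the 6 that rose and 1 of the 3 that fell were called. Col1a2 was not called without vehicle 1 (2.19, adjusted p = 0.0555), and Ogn, Lox and Col1a2 were not called with chip as a fixed block (2.13 ± 0.59, 2.90 ± 0.68 and 1.996 ± 0.872, adjusted p = 0.0774, 0.0532 and 0.195).

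The sterol and glycolysis lists were not called. Of 23 sterol and fatty acid synthesis genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone). Their mean was -0.023 and median -0.019, while the test pointed up (adjusted p = 0.944). On RAPPD 1 the list mean was 8.191, below the vehicle arrays (8.67 to 8.94), while on RAPPD 2 to 4 it was 8.879 to 9.035. Without RAPPD 1 the mean difference was 0.17 (camera adjusted p = 0.244). The lipogenic regulator Srebf1 fell by 1.38 ± 0.29 and the elongase Elovl6 fell by 1.59 ± 0.41. The call of Elovl6 was lost at a similar size without vehicle 1, 2 or 3 (-1.63, -1.61 and -1.51, adjusted p 0.0694, 0.0596 and 0.0616). Of 26 glycolysis and hypoxia genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone), with a mean of 0.31 (adjusted p = 0.121). It was 0.54 with chip as a fixed block, where the list was called (adjusted p = 0.00290). The vasoactive peptide gene Adm rose by 2.29 ± 0.38 and Ndrg1 by 1.15 ± 0.22. Srebf1 was above background on 2 of the 4 RAPPD arrays and Adm on 2 of the 3 vehicle arrays, so the floor limits the size of these changes. The calls of Srebf1, Elovl6, Adm and Ndrg1 were lost with chip as a fixed block (-1.23 ± 0.47, -1.73 ± 0.70, 1.75 ± 0.56 and 1.40 ± 0.33, adjusted p = 0.154, 0.171, 0.108 and 0.0525).

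The macrophage, lymphocyte, dendritic and mast cell, interferon response and antigen presentation lists were not called. Of 28 macrophage and monocyte genes, 6 rose and 4 fell (8 and 5 adjusted over the list alone; mean 0.16, adjusted p = 0.302). The list was called without vehicle 3 (0.34, adjusted p = 0.0379). The fractalkine receptor Cx3cr1 fell by 2.62 ± 0.19, and the monocyte chemokine Ccl2 rose by 2.10 ± 0.32. Of 34 lymphocyte and NK cell genes in the list, 7 were measured, where 1 rose and 2 fell (1 and 2 adjusted over the list alone, mean 0.042, adjusted p = 0.913). Cd79b fell by 1.58 ± 0.25 and was above background on 1 of the 4 RAPPD arrays, so the floor limits the size of its fall. Cd8b1 fell by 0.77 ± 0.16, from a mean of 11.91 to 11.14. That is bright for a T cell gene in mice without a functional thymus, and whether its probe reports T cells was not tested. Of 12 dendritic and mast cell genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone), with a mean of 0.41 (adjusted p = 0.487) where Cd83 rose by 1.44 ± 0.18. The other member that rose was Hdc, which the neutrophil list also holds. Of 24 interferon response genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone), with a mean of -0.0053 (adjusted p = 0.998). The guanylate-binding protein genes Gbp2 and Gbp3 rose by 1.87 ± 0.19 and 1.12 ± 0.20. Of 23 antigen presentation genes, 5 rose and 2 fell (8 and 3 adjusted over the list alone), with a mean of 0.35 (adjusted p = 0.0567), and the list was called without vehicle 3 or RAPPD 1, 2 or 4 (adjusted p 0.0149 to 0.0476). H2-D1, one of several similar class I genes, rose by 1.08 ± 0.18 and the chaperone Calr fell by 1.23 ± 0.16. The calls of Cd8b1, Gbp3 and H2-D1 were lost with chip as a fixed block (-0.54 ± 0.19, 0.69 ± 0.19 and 1.15 ± 0.27, adjusted p = 0.132, 0.0728 and 0.0547).

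Among further cell type lists, 0 were called. The basal epithelium and skin list had a mean of -0.42 (11 genes, 1 rose and 3 fell, the same adjusted over the list alone, adjusted p = 0.215), and the cornified envelope gene Lor was at least 1.37-fold lower. The member that rose was S100a8, which the neutrophil list also holds. Of 14 luminal genes, 0 rose and 3 fell (0 and 2 adjusted over the list alone). The smooth muscle and pericyte list had a mean of 0.24 (13 genes, 3 rose and 0 fell, the same adjusted over the list alone, adjusted p = 0.487). In it the myosin kinase Mylk rose by 1.81 ± 0.32, and Myh11, undetected on all vehicle arrays, was at least 2.09-fold higher. The adipocyte list had a mean of -0.37 (12 genes, 3 rose and 1 fell, 3 and 3 adjusted over the list alone, adjusted p = 0.913), where Car3 fell by 3.80 ± 0.68 and Dgat2 rose by 1.84 ± 0.34. Car3 is also expressed in skeletal muscle and stood at 10.43 on vehicle 2. The endothelium list had a mean of -0.044, a median of 0.039 and a test that pointed down (25 genes, 2 rose and 3 fell, 1 and 3 adjusted over the list alone, adjusted p = 0.998). The apelin receptor Aplnr fell by 1.65 ± 0.19 and the angiopoietin receptor Tek fell by 0.84 ± 0.16. The nerve and Schwann cell list had a mean of 0.21 (9 genes, 1 rose and 1 fell, the same adjusted over the list alone, adjusted p = 0.410), where Egr2 fell by 1.53 ± 0.33 and Eno2 rose by 1.01 ± 0.29. Egr2 is also in the ERK list and Eno2 in the glycolysis list, so no gene of the nerve list alone was called. The call of Myh11 was lost without vehicle 1, 2 or 3 or RAPPD 4 (adjusted p 0.0517 to 0.0856), and that of Eno2 without vehicle 1 or 2 or RAPPD 2, 3 or 4 (adjusted p 0.0707 to 0.117). The calls of Mylk, Myh11, Dgat2 and Eno2 were lost with chip as a fixed block (1.004 ± 0.304, 1.23 ± 0.60, 1.85 ± 0.55 and 0.79 ± 0.47, adjusted p = 0.0947, 0.236, 0.0903 and 0.315).

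The pathway lists that remain were not called by camera. Apoptosis regulators split evenly (22 genes, 5 rose and 5 fell, the same adjusted over the list alone, mean 0.11, adjusted p = 0.770), where the survival gene Bcl2 fell by 1.12 ± 0.19 and the death receptor Fas rose by 2.06 ± 0.35 (other probes 0.74 to 1.63). Genes controlled by p53 had a mean of -0.056, a median of -0.16 and a test that pointed up (22 genes, 6 rose and 5 fell, 7 and 7 adjusted over the list alone, adjusted p = 0.998). Gtse1, a regulator of p53 expressed late in the cell cycle, fell by 2.93 ± 0.19, and Plk2 rose by 1.08 ± 0.18. Mitochondrial respiration genes had a mean of -0.057 (32 genes, 1 rose and 3 fell, the same adjusted over the list alone, adjusted p = 0.653). In it Idh3a fell by 0.79 ± 0.13 and Uqcrc1 fell by 0.59 ± 0.15. Androgen response and prostate secretory genes had a mean of 0.32 (12 genes, 2 rose and 0 fell, 1 and 0 adjusted over the list alone, adjusted p = 0.215). By fry this list was called higher (adjusted p = 0.0176). The secretory gene Svs4, undetected on all vehicle arrays, was at least 1.87-fold higher. The other member that rose was Ndrg1, which the glycolysis and hypoxia list also holds. The call of Svs4 was lost without any 1 array other than RAPPD 2 (differences 0.86 to 1.24, adjusted p 0.0561 to 0.113). That of Uqcrc1 was lost without vehicle 1 or 2 or RAPPD 2, 3 or 4 (-0.60 to -0.52, adjusted p 0.0547 to 0.0683). The calls of Fas, Idh3a, Uqcrc1 and Svs4 were lost with chip as a fixed block (1.21 ± 0.36, -0.75 ± 0.18, -0.43 ± 0.20 and 1.15 ± 0.58, adjusted p = 0.0891, 0.0534, 0.205 and 0.247).

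Mesenchymal transition genes had a mean of 0.35 (26 genes, 5 rose and 2 fell, the same adjusted over the list alone, adjusted p = 0.0908), where the matricellular genes Ccn1 and Ccn2 rose by 1.61 ± 0.28 and 1.58 ± 0.19. The call of Ccn1 was lost with chip as a fixed block (1.30 ± 0.41, adjusted p = 0.105). The mesenchymal list was called without vehicle 3 (0.48, adjusted p = 0.0407) or RAPPD 1 (0.48, adjusted p = 0.0231). Heat shock and unfolded protein response genes had a mean of -0.28 (26 genes, 0 rose and 7 fell, 1 and 8 adjusted over the list alone, adjusted p = 0.0631), where the chaperone Hsph1 fell by 1.21 ± 0.15. The heat shock list was called lower without vehicle 1 (-0.31, camera adjusted p = 0.0307) and by fry on all arrays (adjusted p = 0.00239). NRF2 targets had a mean of 0.017 (24 genes, 2 rose and 2 fell, the same adjusted over the list alone, adjusted p = 0.913). Haem oxygenase Hmox1 rose by 2.33 ± 0.34 and the glutathione transferase Gsta3 fell by 2.84 ± 0.33. Wnt and stem cell genes had a mean of -0.24 (18 genes, 2 rose and 5 fell, the same adjusted over the list alone, adjusted p = 0.487), where the Notch target Hey1 fell by 1.99 ± 0.24 and the methyltransferase Ezh2 fell by 1.64 ± 0.20. By fry the Wnt and stem cell list was called lower (adjusted p = 0.0161).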

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

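The tests of chip, of cell composition and of other groupings were chosen after the results were seen, and the test on platelet and B cell genes was set before its values, apart from that of Cd79b, were seen.

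Of 126 values (named genes and list means) examined for a RAPPD array far from the other 3, 12 stood out, where chance gives about 1 in 20 (6.3). RAPPD 1 was the outlying array in 10 of them. These values are not independent, since the red blood cell list mean holds the globins and Alas2. The count of 12 against 6.3 therefore does not by itself show an excess over chance. The gap to the nearest array, as a share of the group's range, was 0.985 for the red blood cell list mean (9.44 on RAPPD 1, 10.6 on the others). It was 0.973 for Hbb-bs, 0.952 for Hba-a1, 0.929 for Hbb-bt and 0.883 for Alas2. On RAPPD 2 to 4, Hbb-bs (15.82 to 15.85) and Hba-a1 (15.67 to 15.72) lay near the top of the scale. Compression there can draw these arrays together and raise the share. The gap was 0.957 for S100a9 (11.8 on RAPPD 1 and 13.4 on the others) and 0.919 for S100a8. RAPPD 1 was also lowest for Rad54b (0.858), where all 4 arrays lay below the detection limit, and highest for Eno3 (0.834) and Car3 (0.851). RAPPD 3 was lowest for Idh3a (0.914), by a gap of 8.20 to 8.26, and RAPPD 4 for Ogn (0.894), at 9.14 against 10.5 to 10.7.

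Among 3366 probes with no gene named here that passed the filter, 426 were higher and 261 lower in RAPPD tumours (limma on all 21249 probes). These lie outside the gene counts.

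Genes called between the groups were the first pattern weighed. Only 1 of the 35 splits of the 7 arrays into 3 and 4, the real one, gave as many calls (2671). The highest other split gave 368 and set RAPPD 2, 3 and 4 apart from the rest. With 35 splits the smallest share that can be reached is 0.0286. The count therefore argues against chance in the grouping but cannot exclude it, and the splits do not separate group from chip. A difference between chips is argued against by the 1351 genes called from vehicle 1 and 2 against RAPPD 1 and 2: between vehicle 3 and RAPPD 3 and 4, which share a chip, the median ratio of the differences was 0.806 (quartiles 0.466 and 1.09), with 93.2% of the same sign. That test rests on 1 vehicle array, so an effect of chip on part of the calls stays open.

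The fall of the mitosis genes was the next pattern. A lower share of tumour cells as the whole cause is argued against by 5 luminal genes bright enough in vehicle tumours to show such a fall (Foxa1, Krt18, Krt19, Krt8 and Ppl): their median was -1.81, which is 2.27 log2 units above the mitosis median of -4.07 (95% bootstrap interval 0.59 to 4.33). That interval resamples the genes of each list, not tumours, so it does not measure the spread between tumours. A chip difference is argued against by vehicle 3, whose mitosis list mean lay 3.01 log2 units above the highest RAPPD array on the same chip (SD of the RAPPD arrays 0.059). Fewer dividing tumour cells under the treatment is a hypothesis left open. A smaller share of tumour cells may account for part of the fall, since Krt8 and Krt18 fell too. The whole luminal list differed by -0.76 over all arrays but by -0.18 with chip as a fixed block. On that chip vehicle 3 (6.97) lay within the range of the RAPPD arrays (6.43 to 7.29), so a smaller share is not settled.

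The rise of the neutrophil markers was the last pattern. A lower share of tumour cells, which would raise every host cell type alike, is argued against by a neutrophil median 2.62 log2 units above that of 110 genes of 6 other host cell types (95% bootstrap interval 1.76 to 3.36). The bootstrap intervals here resample genes as if independent, although the neutrophil genes had an estimated correlation of 0.572. They do not measure the spread between tumours. Blood left in the tissue cannot be told apart from cells in the tissue: 14 platelet and B cell genes had a median of 0.584 (interval 0.205 to 0.753), below the rise of 1 log2 unit set beforehand, but 12 of them lay within 3 log2 units of the lowest value, where a rise is compressed, so that limit does not decide. The 2 others were not called (Cd52 0.71 ± 0.33, adjusted p = 0.15, and Ebf1 0.059 ± 0.16, adjusted p = 0.821). Of those near the floor, Cd37 rose by 1.37 ± 0.29, Ppbp rose by 0.95 ± 0.27 and Cd79b fell by 1.58 ± 0.25. The red blood cell list had a mean difference of 1.61, which goes with blood, and on RAPPD 1 both it (9.44, others 10.6) and the neutrophil list (9.08, others 10.19 to 10.61) were lowest of the RAPPD arrays. Among vehicle arrays the 2 lists did not run together: vehicle 3 was highest for neutrophil (8.41) and lay between the others for red blood cell (8.71, others 8.438 and 9.002). A chip difference cannot be told apart either. The neutrophil list kept its call with chip as a fixed block (1.71, camera adjusted p = 5.56e-05), but that rests on vehicle 3 alone, which lay only 0.672 log2 units below the lowest RAPPD array (SD 0.718), and an influx of neutrophils under the treatment stays open as a hypothesis.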

How the results depend on the processing

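Dropping vehicle 2 and 3 together, normexp fitted to the intensities and scaling to the 75th percentile were chosen after seeing the data, while leaving out each array was planned. Apart from the planned fits leaving out each array, named genes kept direction and side of the threshold in 1391 of 1460 alternative values, lost the call in 69 and reversed in 0. List shifts kept both in 570 of 611, lost the call in 24, gained it in 16 and reversed in 1. In the planned fits leaving out each array, named genes kept both in 609 of 633 values and lost the call in 24. List shifts kept both there in 222 of 238, lost the call in 7, gained it in 9 and reversed in 0. A sign change between list values that were not called (28, and 12 in the planned fits leaving out each array) counts among the kept. The repeated fit without vehicle 2 counts in each of these tallies. Most named genes were chosen from the same data by size or p, so their tallies do not stand for all calls. Of the 2671 calls, 1602 to 2341 (60% to 87.6%) were kept when 1 array was left out. The reversed value is skeletal muscle at 0.12 with chip as a fixed block, which removes vehicle 2. Genes higher and lower were 379 and 659 with chip as a fixed block, and 430 and 617 without vehicle 2 and 3; each leaves 1 vehicle array, assumed to vary like the others. They were 508 and 733 at an adjusted p under 0.01, by construction, and 2325 and 2345 over all probes, where a gene can count more than once. Leaving out 1 array gave 752 to 1298 higher and 896 to 1484 lower, and the count moved by over 1.5 times only without vehicle 1 (752 and 896). With an estimated correlation, 0 lists were higher and 2 lower, and the ERK list (-0.80, adjusted p = 0.391) and the ATF4 list (-1.07, adjusted p = 0.275) lost their calls. By contrast, fry called 6 and 7, though not the same lists as camera. It added androgen response (higher), heat shock and Wnt (both lower), and did not call fibroblast or skeletal muscle (fry adjusted p = 0.324 and 0.336). Glycolysis (adjusted p 0.0029 to 0.678 over all alternatives) was called at 0.29 without a filter, 0.39 with the mean of probes, 0.54 with chip as a fixed block and 0.38 without vehicle 2, and ranged from 0.20 to 0.38 when 1 array was left out; the cause was not tested. The share of calls that were higher was 45.5%, between 41.9% and 47.2% over the scalings, and 36.5% with chip as a fixed block. With the submitters' processed values 1108 genes were higher and 1444 lower, and 2114 of the 2671 calls were kept. Sizes depended on the processing too. Over all alternatives the mitosis mean ranged from -3.63 to -1.70, the latter with the submitters' processed values. Plk1 ranged from -5.53 to -2.44 and Cxcl2 from 3.53 to 6.70. Signal over background limits genes near the floor, where fold changes are compressed.

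No paired analysis was possible because the array numbers only follow the order of the series and pair no samples across groups.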

Other observations

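Apart from Cx3cr1 and Ccl2, which the rule fixed beforehand had named, all genes in this part were picked after their values were seen. No explanation was tested for any of them.

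Within the macrophage and monocyte list the called members went both ways. Cx3cr1 fell by 2.62 ± 0.19 on the log2 scale, the mannose receptor Mrc1 fell by 1.22 ± 0.30, Aif1 fell by 1.19 ± 0.25 and the folate receptor Folr2 fell by 0.99 ± 0.21. The co-receptor Cd14 rose by 1.88 ± 0.29, the monocyte chemokines Ccl2 and Ccl7 by 2.10 ± 0.32 and 1.78 ± 0.33, Tyrobp by 1.07 ± 0.29, the protease Ctss by 1.09 ± 0.29 and Apoe by 0.79 ± 0.15. The complement gene C1qa stood at 10.26 in vehicle and 10.34 in RAPPD tumours (difference 0.078 ± 0.24, limma adjusted p = 0.845). With chip as a fixed block, Cx3cr1, Aif1 and Ccl2 were still called and Mrc1, Folr2, Cd14, Ccl7, Tyrobp, Ctss and Apoe were not (-1.53 ± 0.48, -0.94 ± 0.29, 1.27 ± 0.34, 0.94 ± 0.31, 0.57 ± 0.40, 0.89 ± 0.33 and 0.70 ± 0.21, adjusted p 0.069 to 0.393).

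Among apoptosis regulators, the pro-death genes Bmf and Bcl2l11 rose by 1.51 ± 0.46 and 1.10 ± 0.22 while Pmaip1 fell by 0.93 ± 0.23. Among the Wnt and stem cell genes, Id1 fell by 1.75 ± 0.23 and Id2 rose by 1.85 ± 0.34 (other probes 0.48 to 1.33). The intestinal stem cell marker Lgr5 rose by 2.15 ± 0.63, and the aldehyde dehydrogenase Aldh1a3 fell by 2.27 ± 0.51, with its other probe at -0.42. Of these genes Id1 alone was called with chip as a fixed block (adjusted p = 0.0388, others 0.108 to 0.674), where Bmf, Bcl2l11, Pmaip1, Id2, Lgr5 and Aldh1a3 lay at 0.28 ± 0.38, 0.63 ± 0.22, -0.80 ± 0.37, 1.59 ± 0.51, 1.62 ± 1.05 and -1.13 ± 0.62. That fit leaves 1 vehicle array.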
